A study of Mus musculus with 8 samples.

How the data were processed

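RNA from the brains of 8 samples was measured on Clariom S arrays, 1 array per sample, in 4 groups of 2: water without the tail suspension test (TST), water with TST, low-dose rosemary extract (RE) with TST and high-dose RE with TST. Groups and replicate numbers were taken from the sample titles. Another label field calls water without TST the positive control and water with TST the negative control, which the titles do not explain, and the water groups were not exchanged for it. Per the labels' protocols, 7 mice were assigned to each group and treated for 7 days. Per the submitters' description of the design, the arrays were run on duplicate RNA samples of each group, and the authors normalized them with the robust multichip average (RMA) in Transcriptome Analysis Console 4.0.1. The deposited values are on the log2 scale and were kept as deposited, with 2 decimals. They run from 2.76 to 19.79, and 1359 values exceed 16, the limit of a 16-bit scanner; how the authors' software reached such values is not given in the sources used here, so the size of a log2 difference is that of the deposited scale, which may be stretched against the measured intensity. No depth or detection call comes with these values, and the number of arrays limits the precision. The pair of RNA samples of a group may be separate mice or pools, which the labels do not say.

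The table had 22206 rows, no missing values and no control rows. The platform annotation named 19572 rows with 1 gene symbol, 0 with several, and left 2634 unnamed here; all 19572 matched the gene table by gene identifier and 0 symbols changed. The named rows covered 19505 genes. In 254 rows all 8 values equalled those of another row. No coordinates are given because the genome build of the platform is not stated.

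All tests used limma 3.58.1 in R 4.3.3. A linear model with group means was fitted to all 8 arrays with lmFit and eBayes, so that the 4 groups shared 1 estimate of the spread with 4 residual degrees of freedom and a prior of 4.30 degrees of freedom. The median standard error of a difference was 0.292. The 4 contrasts were water with TST minus water without TST, each RE dose minus water with TST, and high minus low dose. Tests were two-sided, with Benjamini-Hochberg adjustment over all rows. The study's own threshold, stated in its design text, is a fold change above 1.2 (0.263 on the log2 scale) with an unadjusted p under 0.05. Any difference among the 4 groups was tested with the moderated F-test.

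Before the data were examined, 42 gene lists (20 of cell types and brain regions, 22 of pathways and complexes) were fixed. Lists with at least 5 measured genes, 41 of the 42, were tested with camera at a preset inter-gene correlation of 0.01 on 1 row per gene, the row with the highest mean, and adjusted over the lists of a comparison. The erythrocyte list had 3 measured genes and was not tested. With camera's estimated correlation, and with fry, 0 lists passed in any of the 4 comparisons; the lowest adjusted p was 0.555, 0.641, 0.709 and 0.972 for the TST, low-dose, high-dose and dose comparisons with the estimated correlation, and 0.159, 0.698, 0.421 and 0.988 with fry. Lists of cerebellar and forebrain markers were added after the data were seen and were used to describe the arrays, not tested between groups. After the data were seen, the estimated correlation was also used in the fits without water with TST replicate 2 or high-dose RE replicate 2, and the largest single-gene differences, list members past the study's threshold and genes reported whatever their values were followed through the fits that left out 1 array. Not every gene that lost the study's threshold in such a fit is named below.

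Named genes followed a rule also fixed beforehand. Rows with 1 symbol, leaving out predicted loci, olfactory, vomeronasal and taste receptors, microRNAs and small nucleolar RNAs, and with the higher group mean above the median of all values, were taken where both arrays of a group lay on the same side of both arrays of the other. Up to 12 per direction (5 for the dose comparison) were named by size of difference among rows at an adjusted p under 0.05 and, where too few passed, from rows past the study's threshold. A further 17 genes were reported whatever their values, as were up to 4 members of each list that passed and of the oxytocin list.

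The alternatives were a replicate block, a fit of only the groups compared, a variance prior with trend and robust estimation, leaving out the dimmest 25% of rows, quantile normalization, leaving out each array in turn, the one-way analysis of variance of the study's methods, and the other list tests. Where an array is left out, its group has 1 array, which is assumed to vary like the other groups. For each comparison the analysis of variance used only the 4 arrays of the groups compared, with 2 residual degrees of freedom. Rows whose replicates are equal in both groups have no analysis of variance and were left out of it. After the data were seen, fits without both arrays with raised cerebellar markers, with the cerebellar marker mean as a covariate, and with crossed replicate numbers were added.

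Whether replicate numbers pair samples was checked by correlating, across rows, the deviations of same-numbered arrays from their group means; the 6 values ran from -0.293 to 0.169, and the labels name no shared animal, litter or day, so the numbers were not taken to pair the samples. Covariances expected from the shared water with TST arrays were simulated in 100 draws and overlaps in 20 draws.

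The functions were tested on simulated data for the high-dose comparison: 200 of 22206 rows were changed by a known log2 difference in 10 draws each. A difference of 1 was recovered at an adjusted p under 0.05 in 0.05% of the rows and at the study's threshold in 86.7%, a difference of 2 in 91.1% and 99.5%, and a difference of 3 in 99.2% and 100.0%. On average 1074.8 unchanged rows passed the study's threshold in the draws with a difference of 1. A shift of 0.5 in the heat shock list among 19505 genes was found in 10 of 10 draws with the preset correlation. With the estimated correlation it was found in 0 of 10, so that test had no power at that size in these draws. The genes were simulated as independent, whereas the estimated correlation of this list in the data was 0.252. The draws therefore do not show that the preset correlation is sound for genes that vary together.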

Results

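Gene expression was measured in brain RNA of male mice of the outbred ICR strain that had received water or rosemary extract (RE) for 7 days. The tail suspension test (TST), in which a mouse is hung by its tail and its immobility is scored, served as the acute stressor and behavioural readout. The labels name the tissue as limbic system and, in another field, as hippocampus. There were 4 groups with 2 arrays each: water without TST, water with TST, low-dose RE with TST and high-dose RE with TST. The low dose was 10 mg/kg. The high dose was 100 mg/kg in the titles and 50 mg/kg in another label field, so it is called high dose here. A label field calls water without TST the positive and water with TST the negative control; the groups here follow the titles, and an exchange of the water groups would reverse the sign of the TST effect and change the controls of the RE effects. The labels do not say whether the 2 RNA samples of a group came from separate mice or from pools of the 7 mice assigned to it, so the p-values measure only the spread between these samples. The deposited values covered 22206 rows on the log2 scale, 19572 of them with 1 gene symbol. Array medians lay between 7.45 and 7.51. Differences are given as log2 differences with the standard error (SE) of the limma fit, n = 2 arrays per group, and the number of arrays limits the precision.

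The array water with TST replicate 2 stood apart from the rest. Across rows, its correlations with the other arrays lay between 0.967 and 0.978. Those among the other 7 arrays lay between 0.983 and 0.993. The pair of arrays of that group differed by more than 1 log2 unit in 2826 rows, against 727, 1439 and 361 rows in the groups water without TST, low-dose RE and high-dose RE. Genes known as cerebellar markers were high on it. Gabra6, a GABA-A receptor subunit of cerebellar granule cells, was at 16.37 against 5.40 on the other array of its group. Cbln1, a synaptic organiser of the same cells, was at 16.44 against 9.64. Water without TST replicate 1 also had raised values, with Gabra6 at 14.31 against 8.42 on replicate 2. The mean of 12 such markers lay 5.01 above its 8-array mean on water with TST replicate 2 and 2.81 above it on water without TST replicate 1. On the other 6 arrays it lay between -1.63 and -0.642. Markers of forebrain excitatory neurons were low on water with TST replicate 2, for example Nrgn at 10.54 against 15.37 on the other array of its group and Tbr1 at 9.25 against 13.65. Water without TST replicate 2 was highest in markers of striatal projection neurons, at 1.53 above the 8-array mean where the next array was at 0.201, and of hypothalamic neurons, at 0.788 where the next was at 0.146. These marker levels bear on every comparison that uses a water group.

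**Figure D1:**
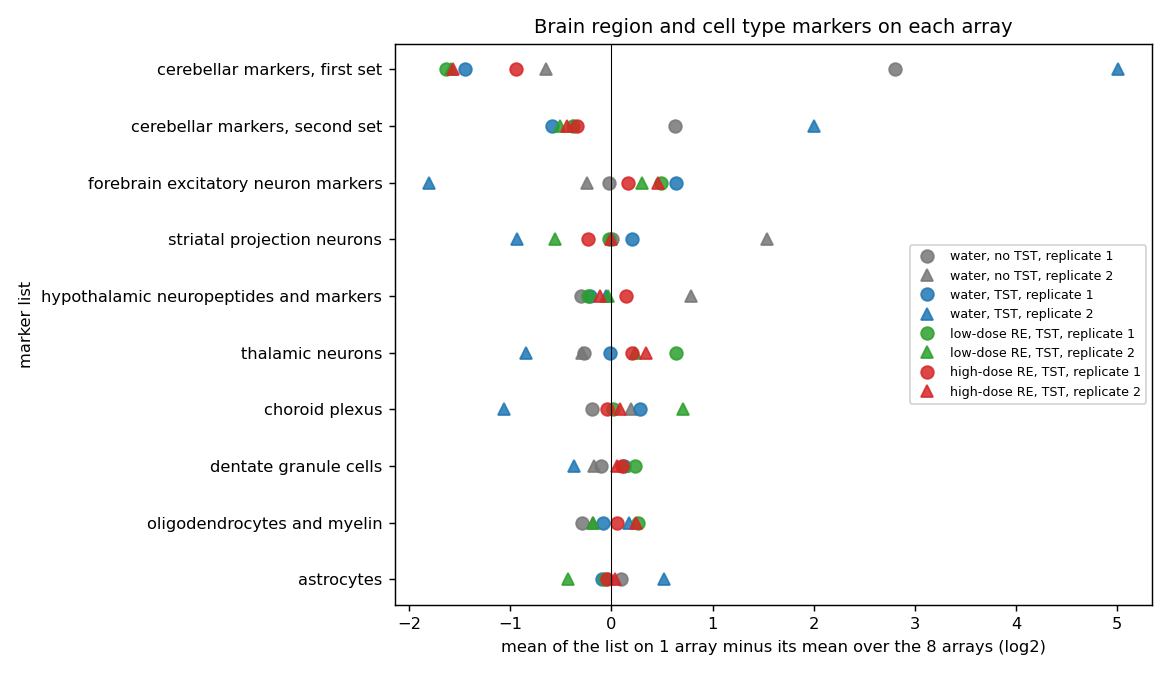
Mean of each marker list on each array minus its mean over the 8 arrays, on the log2 scale (horizontal axis), for 10 lists (vertical axis); each symbol is 1 array, with colour for the group and shape for the replicate. In the first set of cerebellar markers, water with TST replicate 2 lies at 5.01 and water without TST replicate 1 at 2.81, to the right of the other 6 arrays; the cerebellar and forebrain lists were chosen after the data were seen.

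The first comparison asked what the TST changed in mice given water. Markers of striatal projection neurons, the medium spiny neurons of the basal ganglia, fell as a list with TST: the median of 13 measured members was -1.24, 12 were lower, and 4 passed the study's threshold (fold above 1.2 and unadjusted p under 0.05). The phosphodiesterase gene Pde10a passed it at -1.24 (SE 0.442). Not past it were Rgs9 at -2.08 (SE 0.930) and the dopamine receptor genes Drd2 at -1.58 (SE 0.755) and Drd1 at -1.50 (SE 0.713). Opioid and other neuropeptide genes also fell as a list (median -0.557, 17 of 20 lower, 5 past the threshold). Tac1, the substance P precursor, was at -1.43 (SE 0.543) and Penk, the enkephalin precursor, at -1.28 (SE 0.551). Nts, the neurotensin precursor, was at -1.14 (SE 0.389) and the kappa opioid receptor gene Oprk1 at -1.14 (SE 0.386), all 4 past the threshold. In the fit without water without TST replicate 2, Pde10a was at -0.51, Tac1 at -0.525, Penk at -0.45, Nts at -0.485 and Oprk1 at -0.64, none past it. In the fit without water with TST replicate 2, Pde10a was at -0.96, Tac1 at -0.975, Penk at -1.04 and Oprk1 at -0.705, none past it. Nts, at -1.24, stayed past it there. The camera test gave an adjusted p = 1.5e-08 for the striatal list and 1.1e-05 for the neuropeptide list, and adjusted p = 0.576 for both with an estimated correlation. Water without TST replicate 2 was the array highest in the striatal list, and without it neither list passed, with medians of -0.45 and -0.295. Leaving out water with TST replicate 2 gave -0.53 for the striatal list and -0.13 for the neuropeptide list. Each of these fits keeps the other array that is extreme in the striatal list. Its means were 1.53 on water without TST replicate 2 and -0.934 on water with TST replicate 2. On replicate 1 they were 0.0111 without TST and 0.201 with TST, which is no fall.

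In all, 12 lists passed the camera test for the TST effect. Some of them share genes and are not independent of each other. Drd1 and Drd2 are in the striatal and the monoamine receptor lists, and Tac1 and Penk in the striatal and the neuropeptide lists. Tac1, Sst and Cck are in the interneuron and the neuropeptide lists, and Cartpt in the hypothalamic and the neuropeptide lists. Hypothalamic neuropeptides and markers were lower in 18 of 21 (median -0.245, 2 past the threshold, adjusted p = 0.00361). Cartpt passed the threshold at -1.05 (SE 0.390), but not without water without TST replicate 2 (-0.425). It also did not pass without water with TST replicate 1 (-1.095) or replicate 2 (-1.005). Pmch, at -1.38 (SE 1.35), was not past the threshold. GABA-A receptor subunits were lower (median -0.56, 10 of 12 lower, 1 past the threshold, adjusted p = 0.00516), with Gabra3 at -1.38 (SE 0.718) and Gabra4 at -1.25 (SE 0.825). Markers of GABAergic interneurons were lower too (median -0.34, 16 of 20 lower, 3 past the threshold, adjusted p = 0.00458), with Sst, the somatostatin precursor, at -1.04 (SE 0.613). Monoamine receptors and degradation enzymes (median -0.295, 16 of 20 lower, 0 past the threshold, adjusted p = 0.006) had Htr2a at -1.46 (SE 0.748) and Htr2c at -0.86 (SE 0.402). Genes of the unfolded protein response were lower in 15 of 16 (median -0.23, 1 past the threshold, adjusted p = 0.00516), with the chaperone gene Hspa5 at -0.51 (SE 0.215). With any 1 water array left out, Hspa5 lay between -0.57 and -0.45 and was not past the threshold. Nor was it with either high-dose array left out (-0.51). Cytosolic ribosomal protein genes were lower in 33 of 37 (median -0.18, 0 past the threshold, adjusted p = 0.00361), with Rps16 at -0.51 (SE 0.339). Microglial markers were lower in 12 of 17 (median -0.375, 0 past the threshold, adjusted p = 0.0425), with P2ry12 at -1.26 (SE 0.634). Oligodendrocyte and myelin genes were higher in 16 of 18 (median 0.305, 1 past the threshold, adjusted p = 0.00361), with the connexin gene Gjb1 at 0.91 (SE 0.331). Gjb1 was no longer past the threshold without water with TST replicate 2 (0.60) or water without TST replicate 2 (0.72). Mural cell markers were higher in 10 of 13 (median 0.275, 0 past the threshold, adjusted p = 0.00964), with Rgs5 at 0.43 (SE 0.244). With an estimated correlation, the adjusted p of the lists named here lay between 0.555 and 0.796. Without water with TST replicate 2 the hypothalamic and mural lists passed, at -0.47 and 0.28, and the rest named here did not. The microglial and ribosomal medians turned to 0.125 and 0.01 and those of GABA-A receptor subunits, interneurons, monoamine receptors, unfolded protein response and myelin were -0.0475, -0.165, -0.0525, -0.168 and 0.128. Without water without TST replicate 2 only the myelin list of those named here passed and the hypothalamic median was 0.01; the myelin list was lost without replicate 1 of that group (0.205), the hypothalamic (-0.31), mural (0.25) and unfolded protein (-0.315) lists without water with TST replicate 1, and the microglial list with either low-dose array left out, where only the spread changed (median -0.375, adjusted p = 0.0742).

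Oxytocin and vasopressin signalling, a known focus of the study and so not independent evidence of its direction, was lower with TST in 10 of 13 measured genes (median -0.365, 0 past the threshold, 0 adjusted over the list alone). The camera adjusted p was 0.00653, and adjusted p = 0.555 with an estimated correlation. The list did not pass without water with TST replicate 2 (median -0.245, adjusted p = 0.178) or water without TST replicate 2 (median -0.09, adjusted p = 0.510). The prohormone convertase gene Pcsk1 was at -0.725 (SE 0.539), Magel2 at -0.69 (SE 0.357), the oxytocin receptor gene Oxtr at -0.68 (SE 0.373) and Cpe at -0.67 (SE 0.466). Oxt itself was at -0.245 (SE 0.422) and Avp at -0.19 (SE 0.892), both within their error. Of the other genes reported whatever their values, Crh, the corticotropin-releasing hormone gene, was past the study's threshold at -0.73 (SE 0.285). Without water without TST replicate 2, Crh was at -0.34 and not past the threshold. It was also not past it without water with TST replicate 1 (-0.74) or replicate 2 (-0.72), or without either high-dose array (-0.73). The glucocorticoid receptor gene Nr3c1 was at -0.12 (SE 0.290), Fkbp5 at -0.665 (SE 0.515), Bdnf at 0.195 (SE 0.340), Fos at 0.345 (SE 0.331), Egr1 at -0.66 (SE 0.778) and Arc at 0.19 (SE 0.705). The tyrosine hydroxylase gene Th was at -0.835 (SE 0.599), the tryptophan hydroxylase gene Tph2 at 0.72 (SE 0.477) and Maoa at 0.355 (SE 0.355). Gfap was at 0.055 (SE 0.239), Aif1 at -0.555 (SE 0.810), Mbp at 0.25 (SE 0.266) and Ttr, made by the choroid plexus, at -1.52 (SE 0.889).

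Single genes past the study's threshold, none of which passed the adjusted test, were led upward by Foxred2 at 1.32 (SE 0.387), Smarcd2 at 1.31 (SE 0.421) and Neurod2 at 1.23 (SE 0.470). Ccnjl was at 1.20 (SE 0.450), the dentate granule cell regulator Prox1 at 1.10 (SE 0.333) and Atf1 at 1.08 (SE 0.309). The clock repressor gene Nr1d1 followed at 1.06 (SE 0.262) and Dusp1 at 1.06 (SE 0.384), with Dixdc1, Jph1, Cabp7 and Sema7a between 1.005 and 1.035. Downward, Nt5dc3 was at -2.02 (SE 0.769), the dopamine transporter gene Slc6a3 at -1.72 (SE 0.696) and Rxrg at -1.65 (SE 0.602). The glycine receptor subunit gene Glra3 was at -1.48 (SE 0.516) and the galanin receptor gene Galr1 at -1.35 (SE 0.341), with Ecel1, Mme, Gpr52 and Nr2f2 between -1.38 and -1.24. By limma, 0 of the 22206 rows passed an adjusted p of 0.05 (lowest adjusted p = 0.997) and 567 rows had an unadjusted p under 0.05, where 5% of the rows are 1110.3. All 567 also passed the fold limit, 287 higher and 280 lower. The methods' one-way analysis of variance, run on only the 4 arrays of the groups compared, called 0 rows after adjustment. It called 783 at the unadjusted limit and 605 at the study's threshold. Of the 24 largest differences past the threshold, 12 in each direction, 11 shrank by over 1.5 times without water with TST replicate 2. Upward these were Foxred2 to 0.685, Smarcd2 to 0.68, Ccnjl to 0.48, Prox1 to 0.73, Atf1 to 0.68, Dusp1 to 0.665 and Dixdc1 to 0.585. Downward they were Nt5dc3 to -0.63, Glra3 to -0.65, Mme to -0.755 and Nr2f2 to -0.32. Another fit, without water without TST replicate 2, also shrank 11 as much. Besides Tac1, Penk and Pde10a these were Neurod2 to 0.415, Jph1 to 0.52, Cabp7 to 0.455, Sema7a to 0.555, Rxrg to -0.55, Ecel1 to -0.395, Mme to -0.87 and Gpr52 to -0.55. In either of these fits most of the 24 were no longer past the threshold, including some that shrank less. In the fits without water with TST replicate 1 and water without TST replicate 1, 4 and 8 grew as much. With water with TST replicate 1 left out, 512 rows passed the adjusted test and 3707 the study's threshold; with either high-dose array left out, which changes only the spread here, 364 passed that threshold.

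The next comparison set low-dose RE against water, both with TST, and asked which genes the extract changed under the stressor. Thalamic neuron markers rose as a list: the median of 14 genes was 1.19, 12 were higher, 7 passed the study's threshold and 1 was significant when adjusted over the list alone. Tcf7l2, a transcription factor of thalamic neurons, was at 1.76 (SE 0.431), Synpo2 at 1.89 (SE 0.749), Rgs16 at 1.68 (SE 0.534) and the protein kinase C delta gene Prkcd at 1.62 (SE 0.536), all past the study's threshold. Choroid plexus genes were higher in 16 of 16 (median 0.6, 1 past the threshold), with Ttr at 1.90 (SE 0.889), Kcnj13 at 1.56 (SE 0.878), Kl at 1.40 (SE 0.893) and Clic6 at 1.24 (SE 0.675) not past it. Hippocampal pyramidal cell markers were higher in 11 of 12 (median 0.658, 1 past the threshold), with Ociad2 at 1.34 (SE 0.534) past it and Neurod6 at 1.86 (SE 1.15) not. Immediate early genes, which neurons switch on within minutes of activity, were higher in 19 of 24 (median 0.33, 0 past the threshold), with Egr1 at 1.55 (SE 0.778), Dusp6 at 1.34 (SE 0.647) and Arc at 1.22 (SE 0.705). The camera adjusted p was 1.3e-06 for the thalamic, 2.2e-04 for the choroid plexus, 7.9e-04 for the pyramidal and 0.0119 for the immediate early list, and adjusted p = 0.641 for each of the 4 with an estimated correlation. Water with TST replicate 2 was the lowest array in these lists, with list means of -0.846 (thalamic), -1.06 (choroid plexus), -1.07 (pyramidal) and -0.841 (immediate early) against the 8-array mean. Without it the thalamic list passed at 0.455 while the choroid plexus, pyramidal and immediate early lists did not, at 0.065, 0.075 and 0, and Ociad2 was at 0.405 and no longer past the threshold. The choroid plexus list was lost without low-dose RE replicate 2 (0.125), the pyramidal list without replicate 1 (0.422) and the immediate early list without either (0.407 and 0.388).

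Astrocyte markers were lower with low-dose RE (15 of 17 lower, median -0.375, 3 past the threshold, adjusted p = 7.2e-04), as were meningeal fibroblast markers (13 of 16 lower, median -0.473, 2 past the threshold, adjusted p = 7.2e-04). Also lower were monoaminergic neuron markers (12 of 17 lower, median -0.445, 0 past the threshold, adjusted p = 0.0119) and oxidative phosphorylation genes (40 of 56 lower, median -0.12, 0 past the threshold, adjusted p = 0.0486). With an estimated correlation their adjusted p lay between 0.641 and 0.690. The glutamate transporter gene Slc1a3 passed the study's threshold at -0.865 (SE 0.272), and the bicarbonate transporter gene Slc4a4 was at -1.94 (SE 0.890) without passing it. Ptgds, the prostaglandin D synthase gene, was at -1.46 (SE 0.478) and Ogn at -1.28 (SE 0.405), both past it. The serotonin transporter gene Slc6a4 was at -1.38 (SE 0.736), Ret at -1.04 (SE 0.640) and Atp5e, of the ATP synthase, at -0.57 (SE 0.251). Without water with TST replicate 2 the meningeal list passed at -0.448, the astrocyte (-0.135) and oxidative phosphorylation (0) lists did not, and the monoaminergic median turned to 0.075; Slc1a3 was at -0.525 and no longer past the threshold. The meningeal list was lost without water with TST replicate 1 (-0.36), the monoaminergic list without low-dose RE replicate 1 (-0.33) and the astrocyte list without low-dose RE replicate 2 (-0.24), and the oxidative phosphorylation list without low-dose RE replicate 2 (-0.025). That list was near the limit: its median stayed at -0.12 without either array of water without TST (adjusted p = 0.057), without either high-dose array (adjusted p = 0.0518) and with a replicate block (adjusted p = 0.0546), where it no longer passed, nor did it with quantile normalization (-0.108, adjusted p = 0.150). The oxytocin and vasopressin list did not pass (7 of 13 higher, median 0.265, adjusted p = 0.209). In it Oxtr was at 0.69 (SE 0.373), Pcsk1 at 1.12 (SE 0.539), Cpe at 0.84 (SE 0.466) and Pam at 0.73 (SE 0.396), with Oxt at -0.495 (SE 0.422) and Avp at -0.46 (SE 0.892).

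Single genes past the study's threshold and not past the adjusted test were, upward, Cwc22 at 2.98 (SE 1.28), the complement protease gene Masp2 at 2.80 (SE 0.658) and Nt5dc3 at 2.11 (SE 0.769). Lrrtm1 was at 1.72 (SE 0.703), the somatostatin receptor gene Sstr2 at 1.72 (SE 0.672), Npnt at 1.62 (SE 0.645), Rorb at 1.52 (SE 0.612) and Evc2 at 1.40 (SE 0.445). The Cwc22 values of the pair of low-dose arrays were far apart, with an SD of 3.63 around 11.14. Downward there were Slc1a6, itself a cerebellar marker, at -2.64 (SE 1.14), Adamts18 at -2.50 (SE 1.04), Fgf1 at -2.01 (SE 0.568), and Btg1 at -1.95 (SE 0.764). Dusp5 was at -1.82 (SE 0.720), Sgpp2 at -1.78 (SE 0.708), H4c3 at -1.77 (SE 0.606) and Stk17b at -1.76 (SE 0.748). The calcium-binding protein gene Calb1 was at -1.61 (SE 0.656), Cdon at -1.46 (SE 0.545) and the intermediate filament gene Vim at -1.43 (SE 0.588). Crh, Fos, Nr3c1, Fkbp5, Bdnf, Th, Tph2, Maoa, Gfap, Aif1 and Mbp did not pass the threshold, with Maoa at -0.725 (SE 0.355) and Bdnf at 0.505 (SE 0.340). By limma 0 rows passed the adjusted test (lowest adjusted p = 0.946) and 787 had an unadjusted p under 0.05, all of them past the fold limit, 430 higher and 357 lower. The methods' one-way analysis of variance gave 0 adjusted, 619 unadjusted and 487 at the study's threshold. Of the 12 largest lower values past the threshold, 10 were highest of the 8 arrays on water with TST replicate 2, and 9 of these 10 were next highest on water without TST replicate 1, the other array with raised cerebellar markers. Of the 12 largest higher values, 11 were lowest on water with TST replicate 2. Leaving that array out shrank 21 of the 24 differences by over 1.5 times, all but Cwc22, H4c3 and Ptgds, and left 5 of the 24 past the study's threshold: Masp2, Tcf7l2, Fgf1, H4c3 and Ptgds. No longer past it were, among others, Adamts18 at -0.755, Slc1a6 at -0.555, Stk17b at -0.425, Calb1 at -0.405 and Rorb at 0.355. In the fit without low-dose RE replicate 2, 3 shrank as much, Cwc22 to 0.415, Sgpp2 to -1.135 and Ptgds to -0.90. With either low-dose array left out, most of the 24 were no longer past the study's threshold. H4c3 shrank to -1.01 without water with TST replicate 1. With water with TST replicate 1 left out, 958 rows passed the adjusted test and 3767 the study's threshold. With low-dose RE replicate 1 left out these were 8 and 1724, and with either high-dose array left out, which changes only the spread here, 496 passed the study's threshold.

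High-dose RE was set against water in the same way. Heat shock protein genes, which encode chaperones, rose as a list: the median of 13 genes was 0.415, 10 were higher, 5 passed the study's threshold and 4 were significant when adjusted over the list alone. Hsph1 was at 1.55 (SE 0.497), Hspa1a at 1.41 (SE 0.359), Dnajb1 at 1.31 (SE 0.290) and Hspa1b at 1.27 (SE 0.309), all past the study's threshold. Hspa1a and Hspa1b are near-identical copies, so their signals are not independent. Immediate early genes also rose as a list (median 0.825, 21 of 24 higher, 4 past the threshold). Arc was at 1.85 (SE 0.705), Nr4a1 at 1.30 (SE 0.489) and Fos at 1.06 (SE 0.331), all past it, and Egr1 was at 1.78 (SE 0.778) and Junb at 1.26 (SE 0.581) without passing it. Thalamic neuron markers rose as well (median 0.9, 12 of 14 higher, 5 past the threshold), with Tcf7l2 at 1.58 (SE 0.431), Rgs16 at 1.44 (SE 0.534), Prkcd at 1.26 (SE 0.536) and, not past the threshold, Synpo2 at 1.66 (SE 0.749). The camera adjusted p was 3.9e-06 for the heat shock and the immediate early lists and 6.5e-06 for the thalamic list, and adjusted p = 0.709 for each with an estimated correlation. Water with TST replicate 2 was the array lowest in all 3 lists; without it the heat shock list passed at 0.375 and the thalamic list at 0.335, and the immediate early list did not pass at 0.185. In that fit Arc was at 0.74, Nr4a1 at 0.62 and Prkcd at 0.40, none past the threshold. Among the fits that left out 1 array, Prkcd was past it only without water with TST replicate 1. Arc, at 1.85, was not past it with either low-dose array left out, which changes only the spread here. Without high-dose RE replicate 2, Arc was at 1.05, Nr4a1 at 0.90 and Fos at 0.57, none past it. The heat shock median was 0.745 without water with TST replicate 1 and 0.275 without high-dose RE replicate 2, and passed in both.

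**Figure D2:**
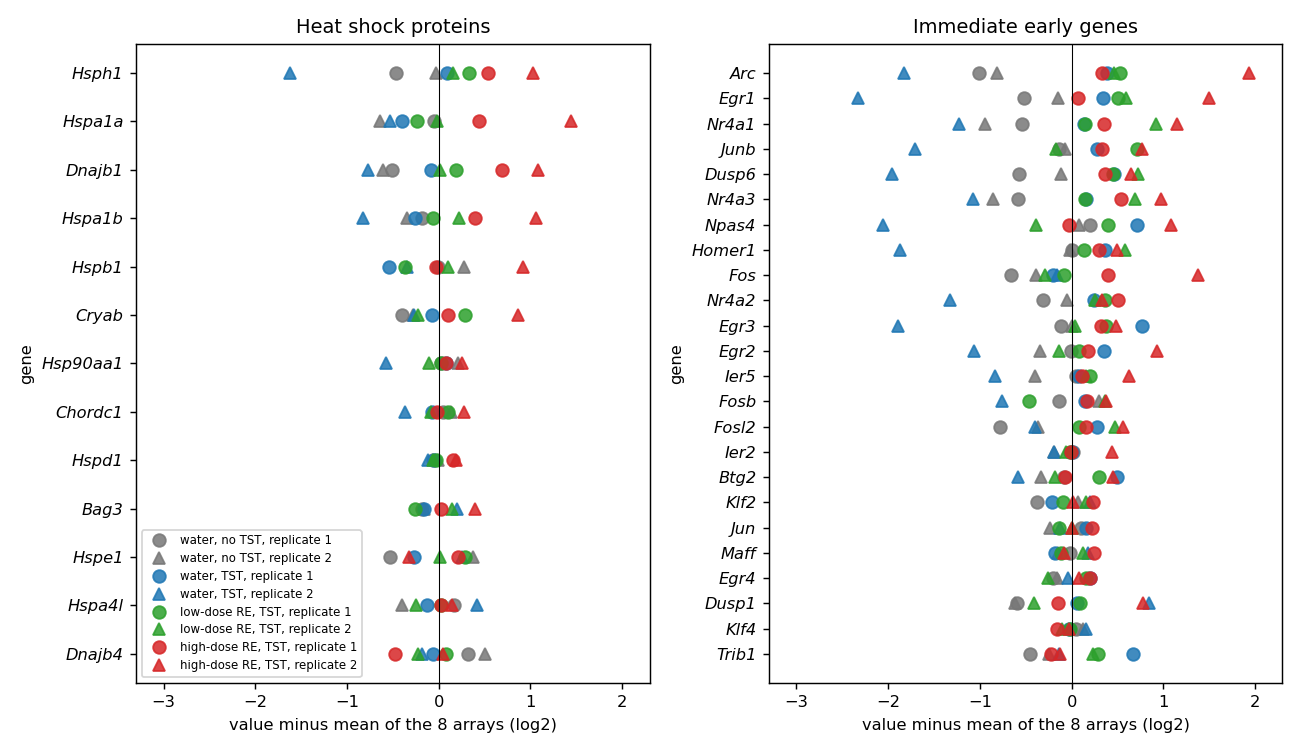
Value of each measured gene of the heat shock list (left) and the immediate early list (right) on each array, minus the gene's mean over the 8 arrays, on the log2 scale; each symbol is 1 array, with colour for the group and shape for the replicate. High-dose RE replicate 2 lies to the right in both panels, with list means of 0.565 and 0.616, and water with TST replicate 2 lies to the left, with list means of -0.365 and -0.841.

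Cytosolic ribosomal protein genes were higher with high-dose RE in 33 of 37 (median 0.225, 0 past the threshold, adjusted p = 5.4e-04), with Rpl22 at 0.60 (SE 0.288) and Rps16 at 0.575 (SE 0.339). Opioid and other neuropeptide genes were higher in 16 of 20 (median 0.417, 1 past the threshold, adjusted p = 0.00985), with Cartpt past it at 1.24 (SE 0.390) and Cck at 1.48 (SE 0.919) not. Meningeal fibroblast markers were lower in 13 of 16 (median -0.298, 1 past the threshold, adjusted p = 0.0356), with Ogn past it at -1.08 (SE 0.405) and Dcn at -1.08 (SE 0.484) not. All 3 had an adjusted p = 0.709 with an estimated correlation. Without water with TST replicate 2 the meningeal list passed at -0.445, the ribosomal list did not at 0.04, and the neuropeptide median turned to -0.0775. The meningeal list was lost without water with TST replicate 1 (-0.28) and high-dose RE replicate 2 (-0.232, with Ogn at -0.635 and not past the threshold), and the neuropeptide list without high-dose RE replicate 1 (0.337). The oxytocin and vasopressin signalling list did not pass (9 of 13 higher, median 0.305, adjusted p = 0.148), except without high-dose RE replicate 2 (median 0.65, adjusted p = 0.0253, and adjusted p = 0.772 with an estimated correlation). In it Pcsk1 was at 1.14 (SE 0.539), Cpe at 1.03 (SE 0.466), Pam at 0.71 (SE 0.396), Avpr1b at 0.48 (SE 0.287), Oxtr at 0.25 (SE 0.373), Oxt at -0.39 (SE 0.422) and Avp at -0.905 (SE 0.892).

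Single genes past the study's threshold and not past the adjusted test were, upward, Nt5dc3 at 2.56 (SE 0.769), Tmem267 at 1.68 (SE 0.398) and Evc2 at 1.60 (SE 0.445). The matricellular protein gene Ccn1 was at 1.52 (SE 0.491), the chromatin remodeller gene Chd5 at 1.52 (SE 0.620), Slc38a6 at 1.40 (SE 0.533), Krt12 at 1.38 (SE 0.399) and Ociad2 at 1.38 (SE 0.534). Downward there were Btg1 at -2.22 (SE 0.764), Bmp1 at -2.16 (SE 0.713), Zic5 at -1.88 (SE 0.804) and Tmtc2 at -1.71 (SE 0.563). Pkib was at -1.68 (SE 0.696), H4c3 at -1.64 (SE 0.606), Cyp2d22 at -1.58 (SE 0.475) and the focal adhesion gene Pxn at -1.53 (SE 0.550). Vim was at -1.52 (SE 0.588), Ddah2 at -1.52 (SE 0.437), Tbata at -1.50 (SE 0.560) and Lin7a at -1.48 (SE 0.541). Crh, Nr3c1, Fkbp5, Bdnf, Th, Tph2, Maoa, Gfap, Aif1, Mbp and Ttr did not pass the threshold, with Ttr at 1.32 (SE 0.889) and Nr3c1 at 0.39 (SE 0.290). By limma 0 rows passed the adjusted test (lowest adjusted p = 0.973) and 705 had an unadjusted p under 0.05, all past the fold limit, 370 higher and 335 lower. The methods' one-way analysis of variance gave 0 adjusted, 847 unadjusted and 649 at the study's threshold. Of the 12 largest lower values past the threshold, 11 were highest of the 8 arrays on water with TST replicate 2 and next highest on water without TST replicate 1, the other array with raised cerebellar markers. Of the 12 largest higher values, 10 were lowest on water with TST replicate 2. Leaving that array out shrank 19 of the 24 differences by over 1.5 times, all but Tmem267, Hspa1a, Slc38a6, Krt12 and H4c3, and left 8 of the 24 past the study's threshold: Nt5dc3, Tmem267, Evc2, Tcf7l2, Hspa1a, H4c3, Cyp2d22 and Ddah2. No longer past it were, among others, Btg1 at -0.95, Hsph1 at 0.695, Vim at -0.46, Zic5 at -0.43 and Chd5 at 0.34. With either high-dose array left out, 11 stayed past it: Hspa1a shrank to 0.91, still past it, and Slc38a6 to 0.725 without replicate 2, and H4c3 to -0.97 without replicate 1. H4c3 also shrank to -0.875 without water with TST replicate 1. With water with TST replicate 1 left out, 928 rows passed the adjusted test and 3785 the study's threshold. That threshold was passed by 354 rows without high-dose RE replicate 1 and by 401 without replicate 2.

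High-dose RE was then compared with low-dose RE. Heat shock genes were higher at the high dose (median 0.275, 11 of 13 higher, 2 past the threshold, adjusted p = 5.7e-04), with Hspa1a at 1.07 (SE 0.359) and Dnajb1 at 0.785 (SE 0.290) past the study's threshold. Dnajb1 was not past it without low-dose RE replicate 2 (0.695) or high-dose RE replicate 2 (0.59). Immediate early genes were higher in 21 of 24 (median 0.19, 1 past the threshold, adjusted p = 0.0313), with Fos past it at 1.08 (SE 0.331) and Arc at 0.635 (SE 0.705) not. Choroid plexus genes were lower in 14 of 16 (median -0.418, 1 past the threshold, adjusted p = 0.0268), with the claudin gene Cldn2 at -0.72 (SE 0.306), or -0.46 and not past the threshold without low-dose RE replicate 2. Monoaminergic neuron markers were higher in 13 of 17 (median 0.245, 0 past the threshold, adjusted p = 0.0268), with Slc6a3 at 1.19 (SE 0.696) and Th at 1.15 (SE 0.599), as were astrocyte markers in 15 of 17 (median 0.23, 1 past the threshold, adjusted p = 0.0268), with Gjb6, a connexin gene, at 0.765 (SE 0.253). Gjb6 passed the threshold, but not without low-dose RE replicate 2 (0.515) or high-dose RE replicate 1 (0.72). With an estimated correlation all 5 lists had an adjusted p = 0.972. Each list was lost without at least 2 of the 4 RE arrays: without high-dose RE replicate 2 the heat shock, immediate early and astrocyte medians were 0.125, 0.0225 and 0.16, and without low-dose RE replicate 2 they were 0.205, 0.22 and 0.145, with choroid plexus at -0.0575. Leaving out high-dose RE replicate 1 gave -0.242 for choroid plexus and turned the monoaminergic median to -0.04, and leaving out low-dose RE replicate 1 gave 0.195 for that list and 0.175 for immediate early genes, none of which passed. The oxytocin and vasopressin list had a median of 0.01 (adjusted p = 0.946), and in it the vasopressin receptor gene Avpr1b was past the study's threshold at 0.71 (SE 0.287), but not without low-dose RE replicate 1 (0.46).

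Other single genes past the study's threshold in the dose comparison were Ikbip at 1.14 (SE 0.310), the glucocorticoid-induced kinase gene Sgk1 at 1.14 (SE 0.383) and Paqr8 at 1.09 (SE 0.377) upward, and Cwc22 at -3.40 (SE 1.28), Masp2 at -1.92 (SE 0.658), Lsmem1 at -1.24 (SE 0.448), Cep89 at -1.15 (SE 0.392) and Tceanc at -1.13 (SE 0.427) downward. Of the genes reported whatever their values, Fos alone passed that threshold here. By limma 0 rows passed the adjusted test (lowest adjusted p = 1) and 425 had an unadjusted p under 0.05, all past the fold limit, 210 higher and 215 lower. The methods' one-way analysis of variance gave 0 adjusted, 812 unadjusted and 559 at the study's threshold. With low-dose RE replicate 1 left out, 8 rows passed the adjusted test and 1183 the study's threshold. Without high-dose RE replicate 2, Fos was at 0.58, Hspa1a at 0.57 and Lsmem1 at -0.78, none past the threshold. Cep89 was at -0.535 and not past it without high-dose RE replicate 1, and Cwc22 was at -0.835 and still past it without low-dose RE replicate 2. Of the 10 largest differences past the threshold, 3 stayed past it when either high-dose array was left out, 4 without low-dose RE replicate 1 and 5 without replicate 2. That threshold was passed by 714 rows without low-dose RE replicate 2 and by 247 without high-dose RE replicate 1.

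**Figure D3:**
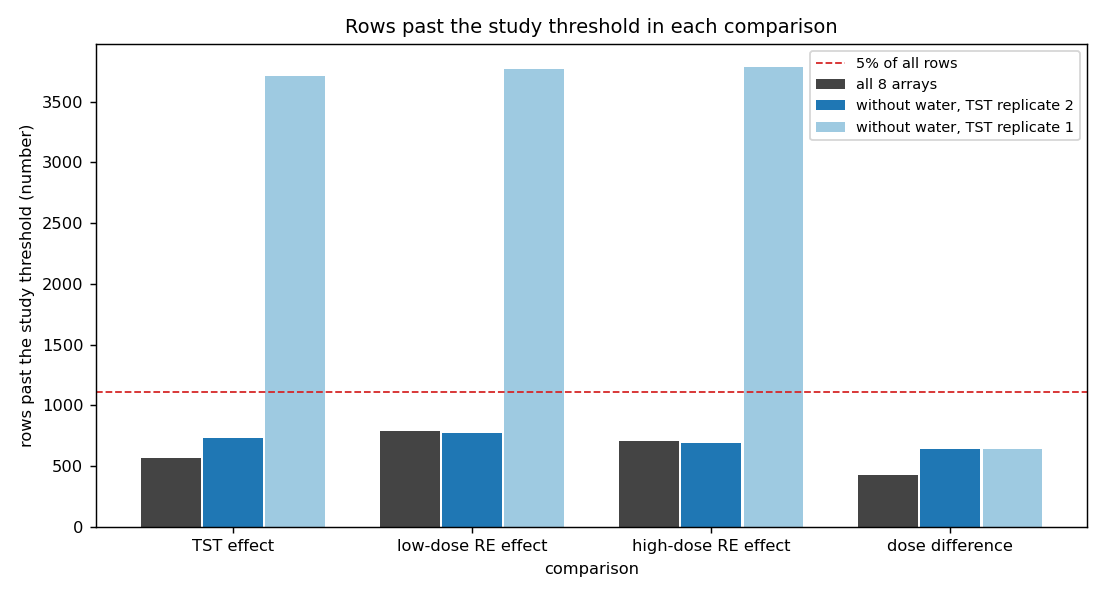
Number of rows past the study's threshold (vertical axis) in each comparison (horizontal axis), with all 8 arrays and without either array of the group water with TST; the dashed line is 5% of all rows, 1110.3. With all 8 arrays the counts were 567, 787, 705 and 425, all under the line, and without water with TST replicate 1 they were 3707, 3767, 3785 and 637.

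A test of any difference among the 4 groups, limma's F-test, found 0 rows at an adjusted p of 0.05, with 404 at an unadjusted p under 0.05 where 5% of the rows are 1110.3. The methods' one-way analysis of variance over the 4 groups gave 0 adjusted and 715 unadjusted. Without water with TST replicate 1 the F-test found 356 rows and without low-dose RE replicate 1 it found 8. The arrays of the groups compared were fully separated in 27.5%, 25.0%, 30.5% and 26.6% of the rows for the TST, low-dose, high-dose and dose comparisons, where chance gives 33.3%.

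The design also allowed the question of whether RE moved genes against the direction of the TST effect. Across rows, which are not independent replicates, the covariance of the TST effect with the low-dose effect was -0.0892 and with the high-dose effect -0.0933 (r = -0.608 and -0.660), and that of both RE effects was 0.124 (r = 0.761). All of these comparisons share the water with TST arrays. Simulated groups with no effect gave covariances of -0.0589, -0.0591 and 0.0590 with 1 pooled spread per row and of -0.148, -0.148 and 0.147 with each group's own spread, so the observed covariances lay between both kinds of simulation. The correlation of both RE effects lay above that of either simulation, the higher of which was 0.733. Of the 280 rows lower with TST at the study's threshold, 63 were among the 430 higher with low-dose RE and 68 among the 370 higher with high-dose RE, where independent lists would share 5.42 and 4.67 and simulated groups with no effect shared 128.0 and 122.8. Of the rows higher with TST, 67 were lower with low-dose RE and 60 with high-dose RE, against 4.61 and 4.33 for independent lists and 125.4 and 124.4 with no effect. Both RE doses shared 97 higher and 100 lower rows, against 7.16 and 5.39 for independent lists and 128.8 and 124.2 with no effect. Each observed overlap was smaller than that simulated with no effect, but the lists were not matched in length. In the simulated high-dose comparison with a difference of 1, 1074.8 unchanged rows passed the study's threshold on average, against 705 rows observed. The counts therefore cannot decide whether the shared arrays alone give the overlap. With 2 arrays in the group water with TST, no part of it could be set apart.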

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

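The tests in this part were chosen after the results were seen, except the count over partitions of the arrays. In 5 of the 41 lists the effect of high-dose RE differed from that of low-dose RE by the camera test of the difference itself: choroid plexus genes by a median of -0.418, monoaminergic neuron markers by 0.245, immediate early genes by 0.19, astrocyte markers by 0.23 and heat shock genes by 0.275. None of the 5 passed with an estimated correlation (adjusted p = 0.972).

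The array water with TST replicate 2 stood apart, and cerebellar tissue in that RNA is a candidate source. Of 14 measured cerebellar markers not among those by which the array was noticed, 13 were highest on it, and 10 were second highest on water without TST replicate 1 with no tie. For 7 of the 14, the mean over the other 7 arrays was above the median of all values. The tissue may thus express them too. This cannot be settled, since there are no detection calls and the 7 arrays include water without TST replicate 1. Another list holds 1 of the 14. Of the first set, Zic1, Cbln1 and Gabra6 were at 17.17, 16.44 and 16.37 on it, against 12.80, 9.64 and 5.40 on the other array of its group. The TST itself as the source is argued against by 1 array only. The other array of the group lay below water without TST in these 14 markers (mean difference -0.709, SE over markers 0.144). Against replicate 2 of water without TST alone, the mean difference was -0.204 (SE over markers 0.0992). Markers on 1 array are not replicates, so these SEs do not measure the spread between arrays. Scaling of the array is argued against, since the gap of 2.28 to the other arrays was 2.29 after quantile normalization. How cerebellar RNA would have entered, by dissection or by an exchange of samples, was not tested, and a biological difference between the mice stays open.

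Immediate early genes were higher with high-dose RE than with water at a median of 0.825. Without water with TST replicate 2 the median was 0.185 and the list no longer passed (adjusted p = 0.380), so most of the difference may come from that array. A response in both high-dose arrays stays open: against water with TST replicate 1, high-dose replicate 1 differed by a mean of -0.0542 (SE over genes 0.0734) and replicate 2 by 0.379 (SE 0.114). With a single control array left, this cannot be told apart from variation between arrays.

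Genes of heat shock proteins were higher with high-dose RE than with water at a median of 0.415. The cerebellar array as the whole cause is argued against by the median without it, 0.375, at which the list passed at the preset correlation (adjusted p = 1.7e-04) and not with an estimated correlation (adjusted p = 0.792). Whether high-dose replicate 2 was the whole cause is not decided. The median without it was 0.275, but that fit keeps water with TST replicate 2, the array lowest in this list (list mean -0.365). These 2 arrays were not left out together. High-dose replicate 1 had a list mean of 0.165 against -0.15 on water with TST replicate 1, with 1 array each. Against low-dose RE, the median without high-dose replicate 2 was 0.125. High-dose replicate 2 was the higher of its pair, with a list mean of 0.565 against 0.165 on replicate 1. An effect of the extract may remain as a hypothesis; handling and time of death, which the labels do not give, were not tested.

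In the test of any difference among the 4 groups, 404 rows had an unadjusted p under 0.05. Of 100 drawn from the 105 partitions of the 8 arrays into 4 pairs, the real one included, 97 gave as many rows, so chance cannot be excluded; the highest other partition gave 2289. The 15 partitions that paired water with TST replicate 2 with water without TST replicate 1 gave a median of 1561 rows, and all 15 gave rows at an adjusted p under 0.05, from 2 to 11. The 14 that paired it with low-dose RE replicate 2 gave a median of 1307 and the rest, the real partition left out, 625.5, with 0 such rows in each. This points to a structure of the samples that the groups do not follow, clearest in the pair with raised cerebellar markers.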

How the results depend on the processing

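The fits without both arrays with raised cerebellar markers, with the cerebellar marker mean as a covariate, with crossed replicate numbers, and with an estimated correlation where 1 array is left out were chosen after seeing the data. Leaving out 1 array moved the counts of rows most, and the other list tests took the counts of lists to 0. At an adjusted p under 0.05 the count ran from 0 to 512 for the TST effect, 0 to 958 for the low dose, 0 to 928 for the high dose, 0 to 8 for the dose difference and 0 to 356 for any difference among the 4 groups. The highest values, except that of the dose difference, came without water with TST replicate 1, which leaves the array with high cerebellar markers as the single array of that group. At the study's threshold the counts ran from 364 to 3707 (TST), 496 to 3767 (low dose), 354 to 3785 (high dose) and 247 to 1183 (dose difference). The number of lists passed ran from 2 to 16, 5 to 16, 6 to 20 and 1 to 6 in the same order. The covariance of the TST effect ran from -0.399 to -0.0656 with the low-dose and from -0.403 to -0.0696 with the high-dose effect, and that of both RE effects from 0.0882 to 0.455. Without the dimmest rows they were -0.101, -0.105 and 0.146.

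At the study's threshold, a fit of only the groups compared gave 352 rows (TST) and 267 (low dose), and the methods' one-way analysis of variance 487 (low dose). The fit without the dimmest rows gave 249 (dose difference, fewer rows tested) and the cerebellar covariate 1042 (TST). For low-dose RE, 5 lists passed without both arrays with raised cerebellar markers and 4 with the covariate. With an estimated correlation and with fry, 0 lists passed in any comparison, and 0 did with an estimated correlation where water with TST replicate 2 or high-dose RE replicate 2 was left out. By limma and by the methods' analysis of variance, 0 rows passed the adjusted test in any comparison under the settings that left out no array or both arrays with raised cerebellar markers.

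With a replicate block the study's threshold gave 497, 702, 632 and 409 rows and 13, 7, 6 and 5 lists passed for the TST, low-dose, high-dose and dose comparisons, with 0 rows at an adjusted p under 0.05. The block ended the call of the oxidative phosphorylation list, whose median stayed at -0.12. Same-numbered arrays of the water groups correlated at -0.293 in their deviations, and crossed pairing gave 0 adjusted rows, 689 at the study's threshold and 12 lists for the TST effect.

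Some list medians turned sign. Over the fits that left out 1 array, the TST effect ran from -0.82 to 0.01 for hypothalamic markers, -0.895 to 0.125 for microglia and -0.36 to 0.01 for ribosomal proteins. The low-dose effect ran from -0.545 to 0.075 for monoaminergic neurons, the high-dose effect from -0.0775 to 0.667 for neuropeptides and the dose difference from -0.04 to 0.55 for monoaminergic neurons. Without both arrays with raised cerebellar markers the values were 0.04 for microglia (TST), 0.075 for monoaminergic neurons (low dose) and -0.0775 for neuropeptides (high dose). With the covariate the low-dose effect on immediate early genes was -0.0197. Beyond the arrays left out, the cause was not tested. Of 156 named gene differences not past the study's threshold, 37 changed sign without water with TST replicate 2 and 38 without both arrays with raised cerebellar markers. Of 103 past it, 40 stayed past it without water with TST replicate 2, 102 with quantile normalization and 9 with the methods' analysis of variance. Signal over background was not available for weighing dim rows.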

Other observations

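The choices of array in this part were made after the results were seen. Without water with TST replicate 2, the TST comparison set 1 TST array against the arrays without TST, and 11 lists passed, 3 of them among the 12 that passed with all arrays. Immediate early genes were higher with TST at a median of 0.475 (adjusted p = 1.3e-07) and glucocorticoid-responsive genes at 0.28 (adjusted p = 0.0082). Markers of hippocampal pyramidal cells were at 0.39 (adjusted p = 8.2e-05) and circadian clock genes at 0.193 (adjusted p = 0.013). Markers of monoaminergic neurons were lower at -0.43 (adjusted p = 0.00278). With an estimated correlation 0 lists passed in this fit: the adjusted p was 0.439 for the immediate early, glucocorticoid-responsive and pyramidal lists and 0.766 for the other pair. The tissue markers moved with these lists: forebrain excitatory markers were at 0.639 on water with TST replicate 1, the highest of the 8 arrays, against -0.0185 and -0.243 without TST, and 1 of the arrays without TST had raised cerebellar markers (2.81 in the first set). The mean of the immediate early genes lay at -0.277 and -0.245 on the arrays without TST and at 0.237 on water with TST replicate 1. It was 0.169 and 0.159 with low-dose RE, 0.182 and 0.616 with high-dose RE, and -0.841 on water with TST replicate 2.

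In the same fit, microglial markers had a median of -0.27 with low-dose RE (adjusted p = 0.0489) and -0.21 with high-dose RE (adjusted p = 0.002). Markers of mural cells were at -0.33 (adjusted p = 0.0085) and -0.21 (adjusted p = 0.0307). Striatal markers were at -0.445 with low-dose RE (adjusted p = 0.0115). With high-dose RE, myelin genes were at 0.242 (adjusted p = 0.0307) and markers of hippocampal pyramidal cells at -0.33 (adjusted p = 0.0322). With an estimated correlation these had an adjusted p = 0.880 (low dose) and 0.792 (high dose). All rest on a single water with TST array.

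Among the genes on the lists and those reported whatever their values, Pmch, the melanin-concentrating hormone precursor, had an SD of 3.54 around 9.30 in water without TST, and Avp an SD of 2.10 around 7.12. These SDs were 1.41 and 1.35 in water with TST, 0.163 and 0.00707 with low-dose RE and 0.382 and 0.0990 with high-dose RE.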
